A study of Pyrus pyrifolia with 2 samples.

How the data were processed

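RNA was sequenced from wounded tissue of the sand pear (Pyrus pyrifolia, cultivar Shuijing). Per the labels, 30 μL of a suspension of the yeast Wickerhamomyces anomalus, or 30 μL of sterilized water as the control, was placed in each wound, and fruit was kept at 28 °C and 95% relative humidity for 3 days. Each treatment has 1 library, so there is no replicate spread. No p-value was computed, and every ratio compares these 2 libraries only.

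The gene table deposited by the authors holds FPKM (fragments per kilobase of transcript, scaled to library size) for 46408 rows. Of these, 42341 carry the identifier of an annotated gene (prefix Pbr) and 4067 carry the identifier of a locus assembled from reads (prefix MSTRG). Per the file headers, each library also has a transcript table with the FPKM, the mean coverage per base, the position, the exon number and the length of 57919 transcripts at 45905 assembled loci. HISAT2 and HTSeq 0.6.1 are named in the submitters' processing notes, with no role given. The genome build, the annotation release, the program that wrote the transcript tables and the use of strand are not given in the sources used here, and 1177 transcripts have no strand. Coordinates are those of the deposited tables, 1-based. Every annotated transcript has a length that is a multiple of 3, so the length of an annotated transcript is given as its coding length, without untranslated regions. Loci that also hold assembled transcripts can be longer, and the exon number of a locus is the highest among its transcripts. Exon coordinates are not in the transcript tables used here, so overlap between loci was judged from their spans, introns included.

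The gene table was compared with the transcript tables. For all 31704 rows above 0 in either library, the deposited gene FPKM equalled the sum of transcript FPKM times transcript length over a locus carrying the row's name, divided by a length that was whole to within 0.05 bases. For the 29275 rows above 0 in both libraries, the same length fitted both within 0.1%. The other 14704 rows are 0 in both libraries and do not test this. Where several annotated genes had been merged into a locus, the table repeats the value of the locus for each. Of the rows analysed below, 603 repeat the value of another row. The value of 100 annotated rows comes from another locus with the same gene name than the one that holds the annotated transcript, 92 of them among the analysed rows.

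The depth was taken from the deposited coverage. Coverage divided by FPKM was constant within each library and gave 5810111683 bases behind the water-treated library and 5026055503 behind the yeast-treated library. At transcripts with fewer than 1000 covered bases, coverage times length was most often 300 bases in both libraries. A whole multiple of 150, within 0.5 bases, was found for 14.7% of such transcripts in the water-treated library and 15.3% in the yeast-treated library, against 0.667% by chance. Reads were therefore taken as pairs of 150 bases, and read pairs per locus were estimated as coverage times length over 300. These estimates need not be whole, and no count model was fitted to them. They served for the simulations, for the minimum numbers of read pairs, for the check of loci listed at 0 and for exact (Clopper-Pearson) 95% intervals of ratios, conditional on the sum of the pairs, rounded to whole pairs. Read pairs without molecular identifiers are not independent molecules, so intervals and simulations cover counting error only and say nothing about the spread between fruits.

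Ratios were computed as log2((FPKM yeast + 1)/(FPKM water + 1)), which understates the change of weakly expressed genes. A gene was counted as measured at a mean FPKM of at least 1 over both libraries, and as higher or lower at a log2 ratio of at least 1 or at most -1, which is called 2-fold here. Folds printed with an interval are plain FPKM ratios. A gene at exactly 0 in a library is described as listed at 0, with no fold. The pseudocount, the filter and the 2-fold threshold of this count, its alternatives other than 3 added later, and the rule for named genes were fixed before the data were examined. Also fixed then were 50 gene lists (defence proteins, phenylpropanoid and flavonoid enzymes, hormone pathways, transcription factor families, cell wall enzymes, tissue markers and others), defined by product descriptions. The files do not pair identifiers with gene names or products and no reference was used, so none of the lists could be applied. The rule for named genes then allows the 2 identifiers with the highest and the 2 with the lowest log2 ratio among genes with a mean FPKM of at least 5. Other loci are given by position.

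The groups by gene structure, the regions by position, the runs of neighbours and the transcript shares were chosen after the files were seen. Structural groups used 1 value per locus and were set against 10000 random lists of the same size matched on mean expression in 10 bins (1000 lists, drawn with replacement, for the 3 largest groups), as a description of these libraries. Regions had to overlap no other measured locus, to lie above 0 in both libraries, and to hold at least 20 estimated read pairs in each and a mean FPKM of at least 5. A run was at least 3 consecutive measured loci all at least 1.5-fold higher or all at least 1.5-fold lower, and was set against 1000 shuffles of the ratios within expression bins. Counting error alone was simulated 100 times by drawing Poisson pairs for both libraries from a shared level per locus. Isoform shares were compared at loci with at least 2 transcripts and a summed FPKM of at least 5 in each library.

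The size rule was tested on simulated libraries of the same 22873 loci with 200 changed. It recovered 62.7% of the loci changed 2.5-fold, 91.0% of those changed 4-fold and 98.5% of those changed 8-fold, and called 36 of 22673 unchanged loci. Alternatives were pseudocounts of 0.1 and 5, no filter on low values and a mean FPKM of at least 5, a 4-fold threshold, centring on the median, upper-quartile scaling, conversion to TPM and summed transcript FPKM. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.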

Results

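The transcriptome of wounded pear tissue was profiled by RNA sequencing 3 days after the wounds received either sterilized water or a suspension of Wickerhamomyces anomalus, a yeast studied as a biocontrol agent against fruit decay. The comparison asks which genes of the fruit respond to the yeast, with resistance as the interest of the study. There was 1 library for each treatment. The water-treated library rested on an estimated 19367039 read pairs and the yeast-treated library on 16753518, of which 94.1% and 94.0% were assigned to loci. In the gene table, 30561 rows were above 0 in the water-treated library and 30418 in the yeast-treated library. At these depths, 3 read pairs on a transcript of 1 kilobase correspond to 0.155 FPKM in the water-treated library and 0.179 FPKM in the yeast-treated library.

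The libraries were closely alike. Of 23476 measured genes, 99 were at least 2-fold higher in the yeast-treated library, 94 were at least 2-fold lower, and 23283 (99.2%) lay between. The median log2 ratio was 0.01, and 93.8% of genes had a log2 ratio within 0.5 of 0. Pearson's r of log2(FPKM + 1) across genes was 0.986, where genes are not independent replicates. A ratio of 4-fold or more was reached by 19 genes in the higher and 24 in the lower direction, of which 8 were listed at 0 in the water-treated library and 21 were listed at 0 in the yeast-treated library. With 1 library per treatment, none of these differences has a replicate check. The counts also depended on the pseudocount, with 304 higher and 253 lower genes at 0.1 and 18 higher and 19 lower at 5.

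**Figure D1:**
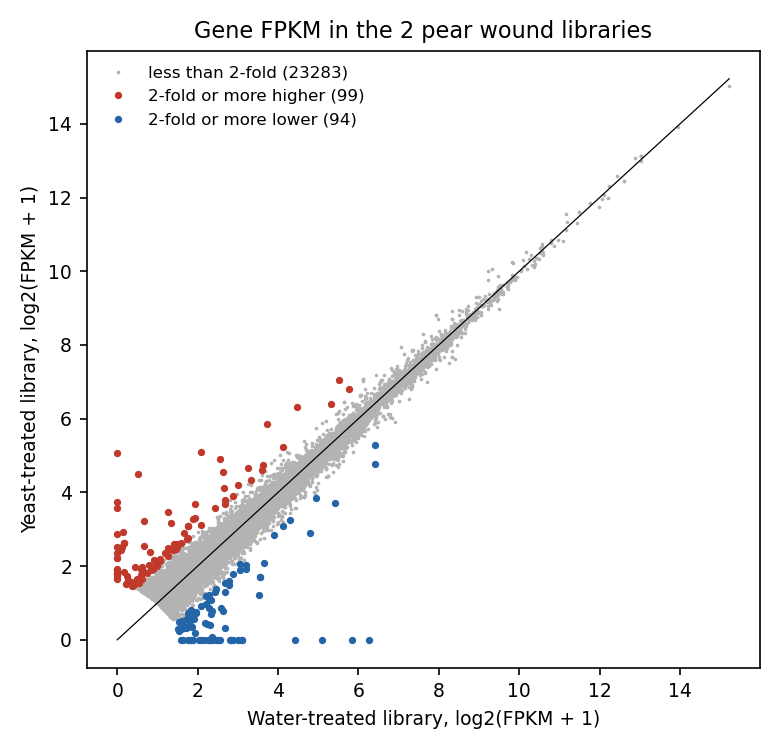
Gene FPKM in the water-treated library (x axis) against the yeast-treated library (y axis), both as log2(FPKM + 1), for 23476 measured genes, 1 point each, with the line of equal values. The 99 genes 2-fold or more higher (red) and the 94 lower (blue) on this scale lie mostly at low FPKM, and some lie on an axis because they are listed at 0 in a library.

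The gene with the highest log2 ratio was Pbr020582, an annotated gene of 2 exons on the plus strand of chromosome 8 (9326537 to 9328073, coding length 1149 bases). It was listed at 0 in the water-treated library and at 32.6 FPKM, about 627 read pairs, in the yeast-treated library. Next was MSTRG.17647, an assembled locus of a single exon with no annotated gene and no strand on chromosome 6 (17693341 to 17694146, 806 bases). Its FPKM was 0.438 in the water-treated library and 21.4 in the yeast-treated library, a 48.9-fold ratio with a 95% counting interval of 22.9 to 119.8. The lowest log2 ratio belonged to MSTRG.1901, an assembled single-exon locus of 532 bases on the plus strand of chromosome 10 (17358961 to 17359492), at 75.5 FPKM in the water-treated library and listed at 0 in the yeast-treated library. An assembled locus on the minus strand has the same start and end, and held 1661 read pairs in the water-treated and 2042 in the yeast-treated library. With both strands summed, this region had a log2 ratio of -0.05. Pbr014198, an annotated gene of 8 exons on the plus strand of chromosome 6 (8494851 to 8496678, coding length 534 bases), was at 55.8 FPKM in the water-treated library and listed at 0 in the yeast-treated library. Values of exactly 0 call for caution, and 3 of these 4 loci have one. With at least 30 read pairs in the other library, 35 loci were listed at 0, while only 4 held above 0 and up to 3 read pairs. Whether reads of Pbr020582 and Pbr014198 were given to similar copies elsewhere was not examined by sequence. The identifiers are not paired with gene names or products in the files, so what these genes encode is not stated.

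Of the 20548 loci that overlapped no other measured locus, 67 were at least 2-fold higher in the yeast-treated library and 67 were at least 2-fold lower. With at least 20 read pairs in each library, 26 of 18439 were higher and 15 lower, and with a mean FPKM of at least 5 as well, 19 of 13111 were higher and 7 lower. The requirement of read pairs in both libraries leaves out loci listed at 0 in either library, to which 15 of the 99 higher and 27 of the 94 lower genes belong. The regions described here are from the last of these sets and were chosen after their values were seen. The largest ratio of FPKM among them was that of an annotated 2-exon gene on the plus strand of chromosome 6 (11713282 to 11714157), at 1.41 FPKM in the water-treated and 9.98 FPKM in the yeast-treated library, a 7.06-fold ratio (95% counting interval 4.55 to 11.3). A 4-exon gene on the minus strand of the same chromosome (10742491 to 10743152) was at 4.84 and 29.1 FPKM, a 6.01-fold ratio (4.30 to 8.79). A 3-exon gene on chromosome 13 (7750982 to 7752958, plus strand) was at 12.1 FPKM in the water-treated and 57.0 FPKM in the yeast-treated library, a 4.70-fold ratio (4.20 to 5.26). On chromosome 4, a 2-exon gene (12138415 to 12139410, plus strand) was at 21.4 and 79.0 FPKM, a 3.70-fold ratio (3.25 to 4.22). On chromosome 14, annotated genes at 12325920 to 12326444 and 12340155 to 12341687, both on the plus strand and 13710 bases apart, were 4.19-fold (2.62 to 7.32) and 4.32-fold (3.54 to 5.33) higher in the yeast-treated library.

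In the lower direction, a single-exon gene on chromosome 11 (5398538 to 5399326, minus strand) was at 8.26 FPKM in the water-treated and 2.80 FPKM in the yeast-treated library, 2.94-fold lower (2.03 to 4.37). A 6-exon gene on chromosome 9 (10380585 to 10386777, minus strand) was at 8.24 and 3.10 FPKM, 2.66-fold lower (2.04 to 3.52), and its log2 ratio of -1.17 became -2.21 with transcript FPKM summed. A 3-exon gene on chromosome 16 (6881091 to 6883382, minus strand) was at 83.8 and 38.2 FPKM, 2.19-fold lower (1.95 to 2.47). A 3-exon gene on chromosome 4 (68964 to 72150, plus strand) was at 29.8 and 13.3 FPKM, 2.24-fold lower (2.03 to 2.48). The rule left out loci whose spans overlap another measured locus, of which 30 were higher and 25 lower. Some of the lower ones had larger ratios than the lower regions named above. On chromosome 9, overlapping annotated genes at 21451462 to 21459419 and 21459199 to 21463320 were 4.10-fold (3.29 to 5.13) and 3.47-fold (2.89 to 4.18) lower. On chromosome 5, an 8-exon gene (5661708 to 5673245, minus strand) was 2.96-fold higher (2.80 to 3.12), at 44.5 and 131.7 FPKM.

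A group of neighbouring genes on chromosome 15 was higher together. Between positions 10401894 and 10484257, 4 consecutive measured loci, all annotated genes of 2 exons on the minus strand with coding lengths of 1167 to 1257 bases, were 2.47-fold (95% counting interval 1.93 to 3.15), 2.02-fold (1.75 to 2.34), 2.11-fold (1.81 to 2.48) and 3.15-fold (2.38 to 4.21) higher in the yeast-treated library. Their FPKM in the yeast-treated library was 10.9, 26.7, 23.6 and 8.92, against 4.42, 13.2, 11.2 and 2.83 in the water-treated library. Of 7 further annotated loci in this span, all under a mean FPKM of 1, a 2-exon gene of 1173 bases was at 0.474 FPKM in the water-treated and 1.47 FPKM in the yeast-treated library, and another of 1173 bases was listed at 0 and at 0.534 FPKM. A small assembled locus on the opposite strand, inside the span of the last gene of the run, was at 1.65 and 1.90 FPKM. This was the only run of 4 or more neighbours among the 22873 measured loci, and 11 of 1000 shuffles of the ratios held such a run.

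**Figure D2:**
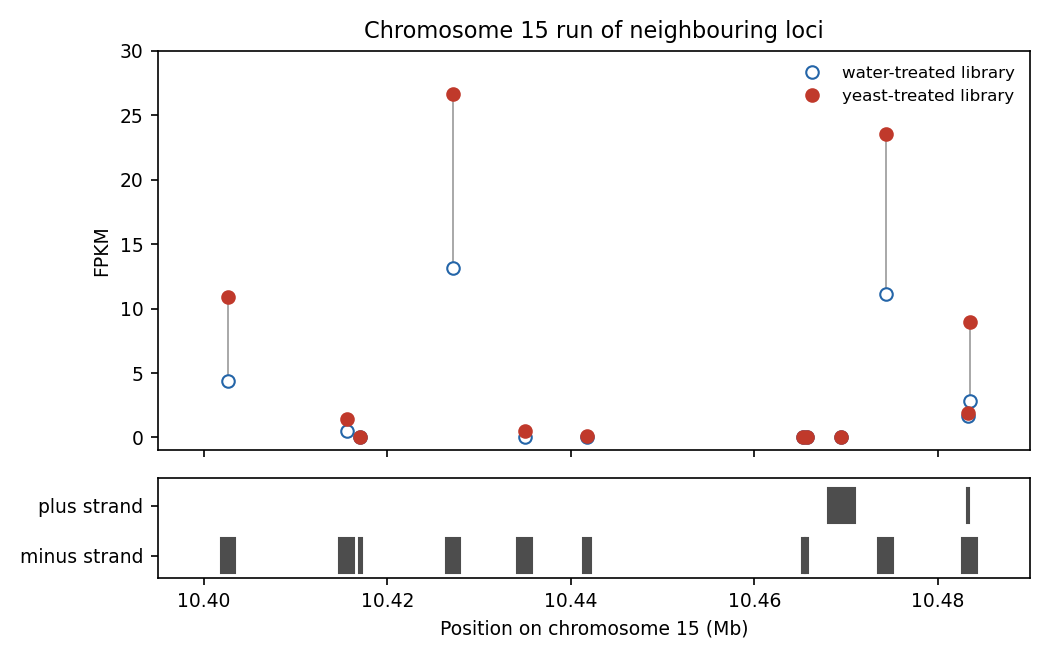
FPKM (y axis) of the loci between 10401894 and 10484257 on chromosome 15 (x axis, position in Mb) in the water-treated library (open circles) and the yeast-treated library (filled circles), with a grey line joining the values of a locus and the spans of the loci drawn to scale by strand below. The 4 genes of the run stand at 8.92 to 26.7 FPKM in the yeast-treated library and at 2.83 to 13.2 FPKM in the water-treated library.

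Ratios past 2-fold were concentrated among weakly expressed loci. With 1 value per locus, 97 of 22873 loci were higher and 92 lower. Of loci with a mean FPKM of 1 to 5, 1.69% were past 2-fold, with 69 higher and 73 lower. The share fell by abundance class to 0.432% at 5 to 20 FPKM, with 22 higher and 13 lower, and to 0.234% at 20 to 100 FPKM, with 6 higher and 6 lower. None of the 1250 loci with a mean FPKM of 100 or more was past 2-fold, and their log2 ratios ranged from -0.79 to 0.97. Library pairs simulated from a shared level with counting error alone gave 17.3 ± 3.73 loci higher and 19.9 ± 4.49 lower (mean ± SD over 100 simulations), nearly all of them at 1 to 5 FPKM. The simulations hold counting error only and give no measure of the spread between fruits or libraries. Of the 193 genes past 2-fold, 52 higher and 52 lower ones had the whole 95% counting interval of the FPKM ratio beyond 2-fold. These include genes listed at 0 in a library, MSTRG.1901 among them, and the interval does not cover reads given to another locus. In the main count, 15 of the 99 higher and 27 of the 94 lower genes were listed at 0.

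**Figure D3:**
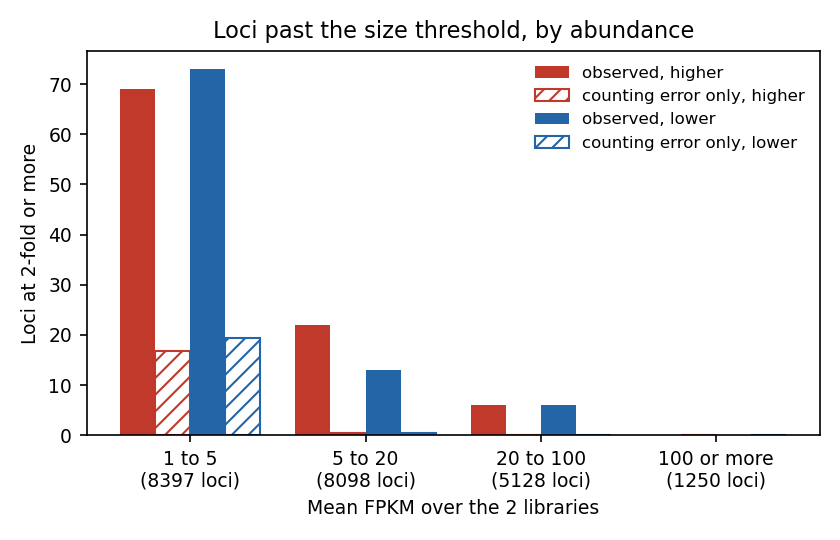
Number of loci at least 2-fold higher (red) or lower (blue) in the yeast-treated library (y axis), by class of mean FPKM (x axis), as observed (filled bars) and as the mean of 100 simulations with counting error alone (hatched bars). At 1 to 5 FPKM, 69 loci were higher and 73 lower against simulated means of 16.8 and 19.5.

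The most abundant locus was an annotated 3-exon gene on the minus strand of chromosome 15 (26372628 to 26373832, coding length 468 bases), at 38190 FPKM in the water-treated and 33565 FPKM in the yeast-treated library, 1.14-fold lower (1.13 to 1.14). The 10 loci with the most read pairs took 11.9% of the assigned pairs in the water-treated library and 11.7% in the yeast-treated library. Of the 10 most abundant loci by FPKM, the log2 ratios lay between -0.21 and 0.19.

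The groups by gene structure that follow were defined after the files were seen, and 10 of them and 17 chromosomes were examined. Assembled loci, which hold no annotated transcript, were past 2-fold more often than annotated genes. Of 3607 such loci, 43 were higher and 49 lower (2.55%), against a mean of 48.9 changed loci in random lists matched on expression (95% of lists between 38 and 61). Here and below, the lists were matched on mean FPKM only, not on length or read pairs. Differences in counting error between short and long loci were therefore not removed, and many of the changed assembled loci are short with few read pairs. Of 19266 annotated loci, 54 were higher and 43 lower (0.503%). Assembled loci made up 48.7% of the loci past 2-fold, and 19.1% of those with a mean FPKM of at least 5. Loci whose span overlapped another measured locus were past 2-fold in 30 higher and 25 lower cases among 2325, where 95% of matched lists held 13 to 30. On unplaced scaffolds, 8 of 3446 loci were higher and 17 lower, and matched lists held 22 to 42 changed loci. Higher and lower loci both occurred on each of the 17 chromosomes. Of 834 measured loci on chromosome 8, 1 was higher and 1 lower. Chromosome 15 had the most measured loci, 2357, of which 13 were higher and 5 lower.

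The number of annotated loci past 2-fold did not follow the number of exons in order. Among single-exon genes, 8 were higher and 7 lower of 2705, where matched lists held 17 to 35 changed loci. Among annotated genes with 2 exons, 19 were higher and 10 lower of 2037, where matched lists held 10 to 25 changed loci. Among genes with 3 to 5 exons, 19 were higher and 17 lower of 5189, where matched lists held 26 to 50. Among genes with 6 or more exons, 8 were higher and 9 lower of 9335, where matched lists held 45 to 76. These lists were drawn from all measured loci, assembled ones included. For annotated loci as a whole they held 117 to 166 changed loci, against 54 higher and 43 lower observed. A count below the range therefore does not by itself set an exon group apart from other annotated loci. The median log2 ratio was -0.06 for single-exon genes, -0.05 for 2-exon genes, -0.02 for genes with 3 to 5 exons and 0.03 for genes with 6 or more. For single-exon genes, 95% of matched random lists had a median between -0.001 and 0.015, and for 2-exon genes between -0.005 and 0.013. For genes with 3 to 5 exons the range was -0.004 to 0.008, and for 6 or more it was -0.001 to 0.008.

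Neighbouring loci had weakly related ratios. For 1098 neighbouring pairs whose spans overlapped, Spearman's rho across pairs was 0.21 and Pearson's r was 0.11, against a shuffled range for rho of -0.06 to 0.06. For 12325 pairs separated by up to 10 kb, rho and r were both 0.05 (shuffled range of rho -0.02 to 0.02). At over 10 and up to 50 kb rho was 0.02 (-0.02 to 0.02), and beyond 50 kb it was 0.01 (-0.04 to 0.05).

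Within loci, transcript shares moved little at most loci and strongly at some. At 6490 loci with at least 2 transcripts, the largest move of a transcript's share had a median of 1.64 percentage points and a 90th percentile of 19.0 points. The transcript with the largest share differed between the libraries at 581 loci (8.95%). A share moved by 50 points or more at 150 loci, and 5 of these were past 2-fold as a locus. At 34 of the 150, a transcript was listed at 0 in a single library, as in both examples below. No counting interval was computed for shares, and how reads were divided among transcripts was not examined. At a locus of 3 transcripts on chromosome 9 (14533303 to 14535861), a transcript of 858 bases took the whole signal (100%) in the water-treated library and was listed at 0 in the yeast-treated library, while the summed FPKM of the locus was 27.1 and 25.4. At a locus of 2 transcripts on chromosome 15 (30969348 to 30977897), a transcript of 2994 bases was listed at 0 in the water-treated library and took 96.1% in the yeast-treated library, with a summed FPKM of 13.1 and 16.4. The log2 ratio from summed transcript FPKM was within 0.1 of that from the gene table for 97.2% of measured genes, for 100% of the 14256 with a single transcript and for 92.8% of the 9220 with more.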

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

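The alternatives with 1 value per locus, above 0 in both libraries, and without overlapping loci were chosen after the data were seen. The count of 99 higher and 94 lower genes depended on settings that act on weakly expressed genes. A pseudocount of 0.1 gave 304 higher and 253 lower, which include all 193 of the main count, and a pseudocount of 5 gave 18 and 19, all among the 193. Without a filter on low values there were 178 and 161, with a mean FPKM of at least 5 there were 28 and 20, and at 4-fold 19 and 24. Conversion to TPM, which raises every value against the pseudocount and the filter, gave 153 higher genes and 134 lower. Centring gave 97 and 96, upper-quartile scaling 98 and 96, 1 value per locus 97 and 92, genes above 0 in both libraries 84 and 67, and loci without overlap 67 and 67. Summed transcript FPKM gave 211 genes, 106 of them higher, which include 189 of the 193. The assembled share of changed loci, 48.7%, was 59.4% without a filter, 36.1% at a pseudocount of 5, 36.6% without overlapping loci and 19.1% at a mean FPKM of at least 5. Of 132 recomputed ratios, 22 per setting and with the mean of the run on chromosome 15 among them, 23 moved by more than the wider side of their counting interval. That criterion was loosened after the labels were seen, and by each interval's own bounds 29 moved. None changed direction. This was largely settled beforehand, since a pseudocount cannot reverse a ratio and the loci had been picked for large ratios. Gene and transcript ratios were within 0.1 for 97.7% of genes with a mean FPKM of at least 5, and the cause of the difference from 97.2% was not tested. The counting interval had a median width (upper over lower bound) of 1.47-fold, and of 1.68-fold for single-transcript genes. No paired analysis was possible because each treatment has 1 library, and no library could be left out. The alternatives for the fixed gene lists were not run, since no list could be applied.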

Other observations

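All tests in this part were chosen after the values had been seen. Besides the run on chromosome 15, 3 further runs of neighbouring loci were at least 1.5-fold higher together in the yeast-treated library, and no run was lower together. On chromosome 11, 3 loci between 4126038 and 4167161 had log2 ratios of 0.59 to 0.82. On chromosome 5, 3 loci between 22321187 and 22787857 had log2 ratios of 0.77 to 0.85, and 3 loci between 23078302 and 23167030, nested within one another's spans, had log2 ratios of 1.09 to 1.35. Of the 4 runs, 3 were without overlap. Shuffled ratios gave 0.474 runs on average and at most 4 in 1000 shuffles, which do not keep overlapping loci alike.

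Some loci were listed at 0 in a single library and held at least 30 estimated read pairs in the other. A mean FPKM of at least 1 was not required. Below it were 878110 to 881234 and 886026 to 891517 on chromosome 4 and 2378955 to 2382569 on chromosome 3. On chromosome 4, the loci at 878110 to 881234, 886026 to 891517 and 1028083 to 1033319 were all listed at 0 in the water-treated library. Listed at 0 in the yeast-treated library were 8494851 to 8496678 and 8504063 to 8507612 on chromosome 6, 2235923 to 2242424 and 2378955 to 2382569 on chromosome 3, and 16082083 to 16086788 and 16392519 to 16393542 on chromosome 17. In all, 35 loci were listed at 0 with at least 30 estimated read pairs in the other library, 13 in the water-treated and 22 in the yeast-treated library.

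Reads given to an overlapping locus are consistent with the values at 3 of these loci, covered by a locus on the opposite strand (median log2 ratio of the summed regions -0.0474) but do not account for most of the 35, since at 30 of them all overlapping loci together held under 50% of the missing read pairs in the library at 0. For 2 loci that overlap others only in part, the summed log2 ratios were 0.16 and -1.05 and this cannot be told apart. The split at a coverage of 50% was set after the value of -1.05 had been seen, and with every overlapping locus counted, 2 of 6 regions were past 2-fold. The others could hardly pass it. They are the 3 covered loci and the region at 0.16, whose overlapping loci held 8422 read pairs against 73 missing. Estimates lost at random over the genome are argued against by 6 pairs of these 30 loci within 500 kb and at 0 in the same library. Of 1000 random draws, 0 reached as many (6 of 1000 for the 2 pairs within 100 kb). The pairs are not separate events, since the loci on chromosome 4 named above pair with one another. Some of the pairs include the loci under a mean FPKM of 1 named above. The draws bear only on loss that is independent of position, and loss at neighbouring loci together was not tested. Reads given to a near-identical copy stay open. An opposite change at a locus of the same length and exon number was found for 5 of the 30, and a change in the same direction for another 5. With 1 library per treatment, the yeast treatment and a difference between fruits stay open and untested.

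The run of 4 genes on chromosome 15 may be a set of neighbouring copies that was higher together. Reads shared by overlapping loci are argued against by the smallest gap between the genes, 7543 bases. A chance order of loci gave a run of 4 or more in 11 of 1000 shuffles. Reads shared between near-identical copies cannot be told apart from a joint change, since the log2 ratios spanned 0.41 and the sequences, which would decide, were not used here. With 1 library per treatment, the yeast treatment and a difference between fruits stay open and untested.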
